A study of Mus musculus with 12 samples.

How the data were processed

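Expression was measured on 12 arrays of 6 groups with 2 arrays each. The groups were Tcf15-E47 cells with 0, 8, 12 and 24 h of dox and parental cells with 0 and 8 h, at 1 µg/mL. Per the labels' protocols, RNA was extracted with an Absolutely RNA kit, and 100 ng was amplified to biotin-labelled cRNA and hybridized to Illumina BeadChips.

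Per the file headers, the non-normalized table the authors deposited holds the average bead signal intensity of each entry on each array, linear and without background subtraction as its values show. Per the file headers it also holds a detection p-value for each entry and array. The deposited table of normalized values is in log2 units and, as its values show, was quantile normalized between arrays without background subtraction, with the median of every array at 6.57 log2 units. Per the labels the authors processed it with limma, with no version given. The deposited table of comparisons holds log2 fold changes and adjusted p-values by the authors for each probe, per the file headers. Its fold changes equal the differences of group means of the normalized values, and its last comparison is parental against Tcf15-E47 cells, the opposite sign to the one used here.

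The 30854 entries of the non-normalized table carry names that match 0 of the 38561 probes of the normalized table. Signals of single probes were therefore recovered by value. Quantile normalization keeps the order of values within an array, so entries were matched to probes on all 12 arrays together, and 17444 entries found a probe. The curve from normalized value to signal was then fitted for each array through the matched entries by isotonic regression (scikit-learn 1.9.0). In a check, 8591 of the matched entries were held out of a refit of the curves. Of these 99.988% found the same probe again, and the recovered log2 signal missed by a median of 3.5e-05. These entries had already been chosen for a clear match, so the check does not cover entries that found no probe. Among the matched entries each of the 12 arrays correlated best with its own column. The match had already paired these columns, so this is no separate check. Detection p-values of probes were read from the matched entries and rounded to the step that 936 negative controls would give. That number was the one implied by the steps of the deposited detection p-values. Of the deposited values, 98.94% in the matched entries and 45.25% in the entries not kept were whole multiples of that step. Background on each array was a mean of 85.87 to 98.75 signal units, the median signal was 88.97 to 103.1, and 30.7% to 34.7% of probes were detected. Signal close to background limits the precision of dim genes.

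Signals were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with background inferred from detection p, offset 16, quantile between arrays). Probes were kept with a detection p under 0.01 on at least 2 arrays, which left 13914. Of all probes, 32093 had 1 gene, 16 several and 6452 none. For 1 probe per gene, the kept probe with the highest mean over all arrays was used, and probes without a gene were tested singly as unnamed, giving 10093 tested genes of which 8537 were named and 1556 unnamed. Symbols were matched through gene identifiers for 32035 probes and 0 changed. Where the probe used was not well above background on either array of the dimmer group, the fold is given only as a bound, the brighter group's mean against the lowest signal among detected probes or the probe's own where higher.

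Group means were fitted over all 12 arrays with limma (lmFit, contrasts.fit, eBayes; two-sided moderated test), with 6 residual and 7.01 prior degrees of freedom and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The 7 comparisons were dox for 8, 12 and 24 h against 0 h in Tcf15-E47 cells, 24 h against 8 h, 8 h against 0 h in parental cells, the difference of both 8 h responses, and Tcf15-E47 against parental cells without dox. The recovery of probe signals by value was not planned and was added when the entry names matched no probe. Apart from that, the samples, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 10 genes with the largest rise and the 10 with the largest fall at 8 h and at 24 h, and 5 and 5 in every other comparison. These were chosen among called genes whose 2 groups of arrays did not overlap, a separation that chance alone gives often with 2 arrays against 2. It also names Tcf15, Tcf3, Id1, Id2, Id3, Nanog, Pou5f1, Sox2, Otx2, Fgf5 and Cdh1 always, and up to 4 called members of each list. Genes named outside the rule are said to be so.

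There were 28 gene lists with 429 entries, of which 225 genes were tested. They covered pluripotency and early lineages, bHLH partners, signalling pathways, stress responses, proliferation and markers of other cells (fibroblast, primitive endoderm, trophoblast, 2-cell-like and germ cell). The 24 lists with at least 5 tested genes went through camera of limma with a preset correlation of 0.01, adjusted over all 168 tests, and again with an estimated correlation. Genes of each list were also counted with the adjustment over the list alone. For pairs of comparisons with the same untreated arrays, 100 simulations of unchanged groups gave the correlation that the shared arrays alone produce.

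The steps were tested on simulated data in which genes were changed by a known fold for the 24 h comparison. The fit called 67.2% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 13 wrong calls among 182. A list shifted in the simulation was called, and 0 lists were called in comparisons without the shifted group. Genes were drawn independently there, so this cannot show how often lists are wrongly called when their genes vary together.

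Alternatives fixed beforehand were no background correction, median scaling, no filter, the normalized values of the authors, trend and robust moderation, only the arrays compared, a replicate block, every kept probe, an added 2-fold limit, an estimated correlation within lists, and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Added after the data were seen were fits without replicate 2 of the parental cells at 8 h, without the 12 h arrays, and on the entries of the non-normalized table themselves. A block for the slide was not run, since the files name no slides. No group has enough arrays for a test of single outlying arrays. Tables were written with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.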

Results

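Gene expression was measured on 12 Illumina BeadChip arrays from mouse E14tg2a embryonic stem cells, an established line. The cells grew in GMEM with fetal calf serum and LIF, the cytokine that keeps such cells undifferentiated. A line carrying a doxycycline (dox)-inducible fusion of Tcf15 to E47, called the Tcf15-E47 cells here, was sampled after 0, 8, 12 and 24 h with 1 µg/mL dox. The parental line without the construct was sampled after 0 and 8 h. Tcf15 is a basic helix-loop-helix (bHLH) transcription factor, and E47 is a product of the gene Tcf3 and a common partner of such factors. Each of the 6 groups held 2 arrays, so n = 2 per group for every value, and no label says whether these were separate cultures. The p values therefore measure only the spread between samples, which may be technical. Median signal per array ran from 88.97 to 103.1 units, over a background mean of 85.87 to 98.75 inferred from detection p-values. Of the probes 30.7% to 34.7% were detected. After normalization the replicates of a group correlated at r = 0.994 to 0.997 across genes, which are not independent replicates. The number of arrays limits the precision.

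After 8 h of dox the question was which genes differ first once Tcf15-E47 is induced. Tcf3 stood at 6.32 normalized log2 units against 5.13 without dox, a difference of 1.20 ± 0.199 (SE; adjusted p = 0.107). Prr19 differed by 0.75 ± 0.101 (adjusted p = 0.0511, the smallest of all genes). Ccno differed by 0.63 ± 0.0956 (adjusted p = 0.0821). Nanog, a core factor of naive pluripotency measured with probe ILMN_2706623, differed by −0.45 ± 0.093 (adjusted p = 0.284). Id3, which binds E proteins and blocks their DNA binding, differed by 0.48 ± 0.0991 (adjusted p = 0.292). Prr19 and Ccno were named here after their values were seen. Otx2 (−0.03), Fgf5 (0.19), Id1 (0.16), Id2 (0.19), Pou5f1 (−0.12), Sox2 (−0.19) and Cdh1 (−0.06) did not pass, each with adjusted p = 0.999. The Tcf15 probe differed by 0.03. Whether the Tcf15 and Tcf3 probes lie within the construct is unknown, so at every time the Tcf3 signal may hold transcripts of the construct itself, which was not tested.

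No gene passed at 8 h: limma called 0 genes higher and 0 lower of 10093, with 435 at an unadjusted p under 0.05 where chance gives 504.7. The count was 3 higher and 1 lower without background correction or from the authors' values. It was 4 and 1 with trend and robust moderation, 1 and 0 with median scaling, and 2 and 0 without the filter or with every kept probe. Fitting only the arrays compared gave 0 and 0. Fitting the entries of the non-normalized table by themselves, an alternative chosen after the data were seen, gave 3 and 0. The deposited test table of the authors called 3 probes higher, of Tcf3, Prr19 and Ccno, and 1 lower, of Nanog. Its called Tcf3 probe was ILMN_2596277, while the Tcf3 probe used here, ILMN_2596278, had an adjusted p of 0.336 there. The 4 genes called when the authors' values were refitted here were Prr19, Ccno, Gadd45g and Nanog, without Tcf3. Nanog passed at an adjusted p of 0.0187 without background correction, 0.0194 from the authors' values and 0.0167 with trend and robust moderation. Tcf3 passed with median scaling and with trend and robust moderation.

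Among the gene lists at 8 h, the list of bHLH dimer partners and Id inhibitors lay above other genes, with a median of 0.18 over 8 genes (adjusted p = 0.00585, and adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 2 of its genes rose. Primitive endoderm genes had a median of −0.16 over 11 genes, or −0.09 with a value against a group not above background at its bound (adjusted p = 0.00585, and adjusted p = 0.564 with an estimated correlation), with 0 called singly. Heat shock genes had a median of −0.11 over 9 genes (adjusted p = 0.0193, and adjusted p = 0.564 with an estimated correlation). Each call was lost when single arrays were left out. For the bHLH list these were replicate 2 without dox and replicate 1 at 8 h, with an adjusted p of up to 0.298. For primitive endoderm they were replicate 1 without dox and replicate 2 at 8 h, up to 0.0932. For heat shock they were both replicates without dox and replicate 1 at 8 h, up to 0.284. Without the filter the primitive endoderm call was lost at 0.196, and the heat shock call was lost there and with median scaling, at up to 0.0912.

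After 12 h of dox, 4 of 14 naive pluripotency genes were lower in the Tcf15-E47 cells, and Otx2, Id3 and Id1 were higher. No parental arrays were taken at 12 h or 24 h. Changes at these times therefore cannot be told apart from effects of dox itself or of time in culture. Nanog fell by 1.14 ± 0.093 on the log2 scale, 2.21-fold (adjusted p = 6.88e-05), from 11.02 to 9.88. Otx2, a factor of the primed epiblast, rose by 0.67 ± 0.102 (adjusted p = 0.00227). Id3 rose by 0.85 ± 0.0991 (adjusted p = 0.000495) and Id1 by 0.44 ± 0.118 (adjusted p = 0.041), which was 0.26 (adjusted p = 0.289) without replicate 2 before dox. Tcf3 rose by 1.40 ± 0.199 (adjusted p = 0.00149).

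The largest rises at 12 h were in Prr19 at 1.71 ± 0.101 (adjusted p = 3.16e-06), Tcf3, Ccno at 1.09 ± 0.0956, Tafa4 and Rxrg, a retinoid X receptor, at 1.02 ± 0.165. Tafa4 was not well above background without dox and was at least 1.79-fold higher. The largest falls were in Dst at −1.41, Kif1a at −1.26, Akap9 at −1.21, Neat1 at −1.21 and Elavl3 at −1.21, with adjusted p values from 6.88e-05 to 0.000387. Dst encodes a cytoskeletal linker, Kif1a a kinesin motor, Akap9 an anchoring protein for protein kinase A, Neat1 a long noncoding RNA of paraspeckles and Elavl3 a neuronal RNA-binding protein. Both arrays of each such gene at 12 h lay beyond both arrays without dox. Fgf5 (0.44, adjusted p = 0.0553), Pou5f1 (−0.30, adjusted p = 0.101), Sox2 (−0.32, adjusted p = 0.122), Id2 (0.15, adjusted p = 0.501), Cdh1 (−0.06) and Tcf15 (−0.04) did not pass.

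**Figure D1:**
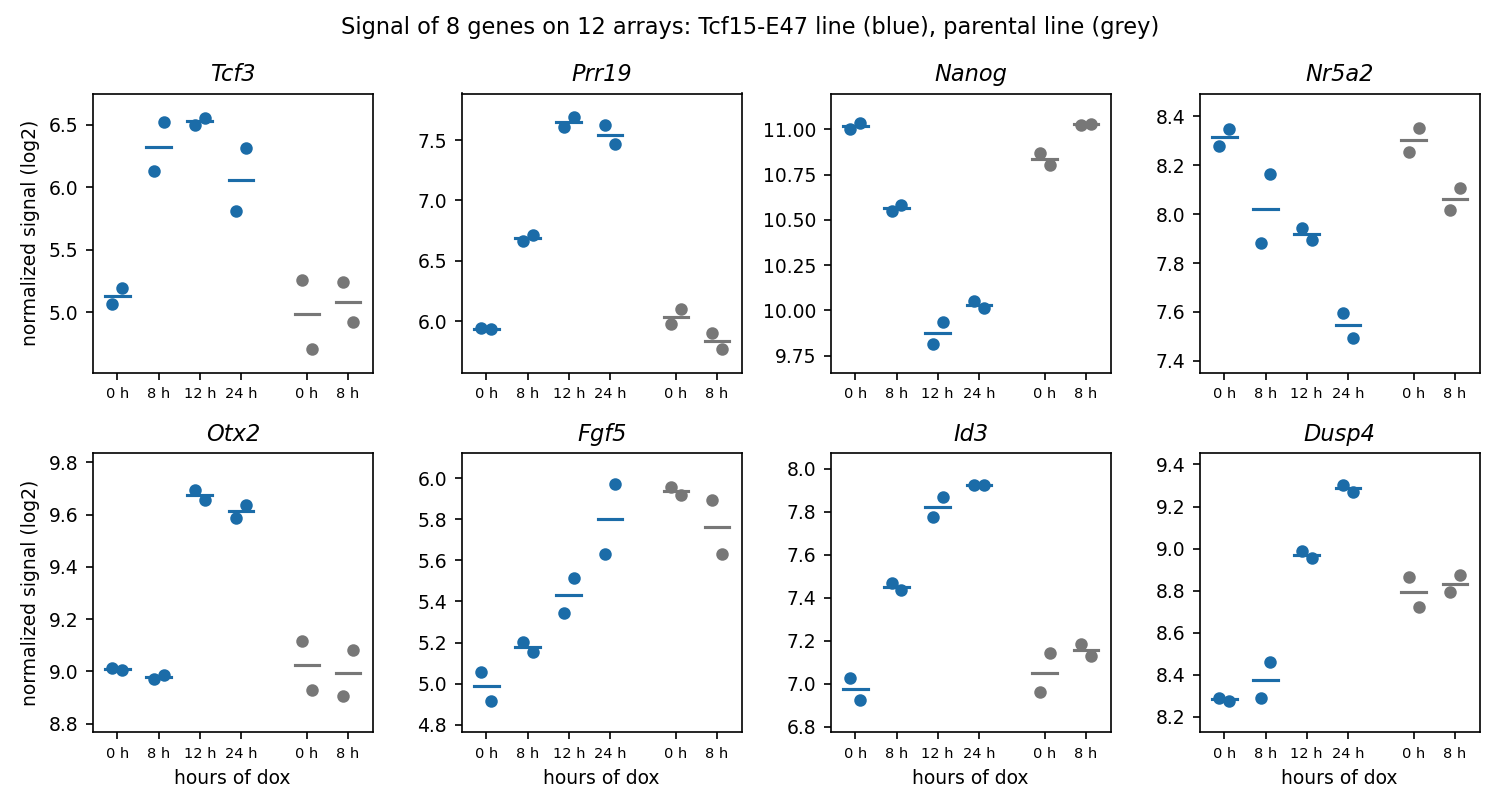
Normalized log2 signal (y axis) of Tcf3, Prr19, Nanog, Nr5a2, Otx2, Fgf5, Id3 and Dusp4 in the 6 groups (x axis), where each point is an array, each bar a group mean, blue the Tcf15-E47 cells and grey the parental cells. Nanog falls from 11.02 without dox to 9.88 at 12 h and 10.03 at 24 h, while Otx2 and Id3 rise.

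Of the 14 naive pluripotency genes measured, 4 fell at 12 h and 0 rose over all genes, and 6 fell adjusted over the list alone. The 4 were Nanog, Tbx3 (−0.66), Tfcp2l1 (−0.47) and Nr5a2 (−0.39). The list's median was −0.30 (adjusted p = 0.000754, and adjusted p = 0.215 with an estimated correlation). All 11 FGF and ERK feedback genes measured had positive values, with a median of 0.30 (adjusted p = 0.0014, and adjusted p = 0.571 with an estimated correlation). The median was 0.28 without 1 gene not above background in either group. Of the 11, Dusp4, a phosphatase that acts on MAP kinases, rose by 0.69 ± 0.0996, and 7 rose adjusted over the list alone. Of 11 primitive endoderm genes, Lama1 (−0.93), Col4a1 (−0.59) and Dab2 (−0.46) fell, also adjusted over the list alone. That list's median was −0.20 (adjusted p = 0.0312, and adjusted p = 0.564 with an estimated correlation). Its call was lost without replicate 1 of either group, at up to 0.0875, and at up to 0.101 without background correction, without the filter and from the authors' values. Of 8 bHLH and Id genes, Id3, Hes6 (0.74) and Id1 rose, and 3 rose and 1 fell adjusted over the list alone, with an adjusted p of 0.185 for the list.

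Other lists at 12 h held called genes without passing themselves. Axin2, a WNT target, rose by 0.65, Utf1 by 0.46, Socs3 by 0.46, Gadd45g by 0.59, Dnajb1 by 0.49, Tex19.1 by 0.48, Phlda3 by 0.47, Ddit4 by 0.44 and Aurka by 0.42. Lefty2 (−0.67), Gadd45b (−0.81), Atf4 (−0.75), Ddit3 (−0.41), Fn1 (−0.57), Tfap2c (−0.53), Map2 (−0.52) and Notch1 (−0.49) fell. Dll1, a NOTCH ligand, was at least 1.58-fold higher and Krt7 at least 1.13-fold higher.

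In all, limma called 307 genes higher and 474 lower at 12 h, with a median size of 0.519 on the log2 scale, and 5 and 20 of them passed 2-fold. The share higher was 39.3%, and 60% with median scaling, which moved the median of all genes by 0.0885 and gave 172 lower. Without background correction 479 were higher, from the authors' values 490 and with trend and robust moderation 466. With a single array left out, counts were 113 higher and 169 lower without replicate 1 before dox, 93 and 181 without replicate 2, 58 and 127 without replicate 1 at 12 h, and 97 and 204 without replicate 2. Of 41 named called genes, 17 passed with any compared array left out, among them Nanog, Otx2, Id3, Tcf3, Prr19, Ccno, Dusp4, Lama1 and Hes6, and 0 reversed. In at least 1 of the 7 settings that refit single genes, the calls of Id1, Tfcp2l1, Nr5a2, Dab2, Col4a1, Fn1, Notch1, Map2, Tfap2c, Gadd45b, Ddit3, Ddit4, Phlda3 and Krt7 were lost and the other 27 held. Pou5f1 passed without background correction, from the authors' values and with trend and robust moderation, at up to 0.0247, and Fgf5 from only the arrays compared, at 0.0371.

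After 24 h of dox, 6 of 14 naive pluripotency genes were lower and 4 of 11 epiblast priming genes were higher than without dox. Without parental arrays at this time, these changes cannot be told apart from effects of dox itself or of time in culture. Nanog fell by 0.99 ± 0.093 on the log2 scale (adjusted p = 0.00018), and Nr5a2, a nuclear receptor of naive cells, by 0.77 ± 0.11 (adjusted p = 0.00252). Fgf5, a marker of the primed epiblast, rose by 0.81 ± 0.129 (adjusted p = 0.00449) and Otx2 by 0.60 ± 0.102 (adjusted p = 0.00657). Fgf5 stood at 5.059 and 4.916 in untreated Tcf15-E47 cells and at 5.633 and 5.969 at 24 h. Untreated parental cells had it at 5.955 and 5.919, so the rise did not take Fgf5 clearly above the parental level. Id3 rose by 0.95 ± 0.0991 (adjusted p = 0.000291), Id1 by 0.63 ± 0.118 (adjusted p = 0.011) and Tcf3 by 0.93 ± 0.199 (adjusted p = 0.022). Pou5f1 (−0.18, adjusted p = 0.358), Sox2 (−0.39, adjusted p = 0.0859), Id2 (0.23, adjusted p = 0.338), Cdh1 (−0.03) and Tcf15 (0.10) did not pass.

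The 10 largest rises at 24 h were in Prr19 at 1.60 ± 0.101 (adjusted p = 6.95e-06), Ramp2 at 1.23 ± 0.131 (adjusted p = 0.000318), Chst1 at 1.15, Pdzrn3 at 1.11, Tmem145 at 1.10, Emp1 at 1.03, Iffo2 at 1.02, Tgfbi at 1.01, Gbp2b at 1.01 and Dusp4 at 1.00. Ramp2 encodes a receptor activity-modifying protein, Tgfbi an extracellular matrix protein and Gbp2b an interferon-inducible GTPase. The 10 largest falls were in Hopx at −1.34 ± 0.1 (adjusted p = 2.72e-05), Gpr83 at −1.21, Mras at −1.17, Lama1 at −1.02, Nanog, the mitochondrial transcript COX2 at −0.98, Myl4 at −0.96, Spen at −0.95, Myo1f at −0.94 and Neurog3 at −0.94. Hopx encodes a homeodomain-only protein, Mras a small GTPase of the RAS family and Lama1 a laminin chain of basement membranes. Adjusted p values of these 20 genes ran from 6.95e-06 to 0.0116, and both arrays of each at 24 h lay beyond both without dox.

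Of the 14 naive pluripotency genes, 6 fell at 24 h and 0 rose, and 8 fell adjusted over the list alone. Beside Nanog and Nr5a2 these were Tbx3 (−0.67), Tcl1 (−0.54, with 0.06 on its other probe), Tfcp2l1 (−0.51) and Prdm14, which was not well above background at 24 h and was at least 1.25-fold lower. The list's median was −0.46, or −0.30 with values against a group not above background at their bound (adjusted p = 4.67e-06, and adjusted p = 0.103 with an estimated correlation). Of 11 epiblast priming genes, Fgf5, Pim2 (0.76), Pou3f1 (0.67) and Otx2 rose, and 4 rose and 1 fell adjusted over the list alone. Their median was 0.12 (adjusted p = 0.0312, and adjusted p = 0.529 with an estimated correlation). That call was lost without replicate 1 before dox and replicate 2 at 24 h, at up to 0.105, without the filter, at 0.187, and from only the arrays compared, at 0.0596. Of 11 general pluripotency genes, Utf1 rose by 0.51 and the list did not pass (adjusted p = 0.743).

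All 11 FGF and ERK feedback genes were positive at 24 h, with a median of 0.33 (adjusted p = 0.000139, and adjusted p = 0.564 with an estimated correlation). The median was 0.31 without 1 gene not above background in either group. Dusp4 and Spry4 (0.52) rose, both feedback inhibitors of the pathway, and 7 rose adjusted over the list alone. Untreated Tcf15-E47 cells had the list below untreated parental cells, with a median of −0.345. Against those parental cells the median at 24 h was 0.146, with 3 of the 11 genes lower. The 8 bHLH and Id genes had a median of 0.24 (adjusted p = 0.00828, and adjusted p = 0.564 with an estimated correlation), with Id1 and Id3 called and 3 rising adjusted over the list alone. Without replicate 2 before dox or replicate 1 at 24 h that call was lost, at up to 0.0771. Lama1 and Sox7 fell among 11 primitive endoderm genes, and also adjusted over the list alone. The Sox7 probe tested was not well above background at 24 h and was at least 1.04-fold lower, with 0.30 on its other probe. That list's median was −0.22, or −0.06 with values against a group not above background at their bound (adjusted p = 0.0312, and adjusted p = 0.564 with an estimated correlation). Its call was lost without replicate 1 before dox and without either replicate at 24 h, at up to 0.109. It was also lost without background correction, without the filter and from the authors' values, at up to 0.293. Of 14 genes of the integrated stress response, Chac1 rose by 0.59, also adjusted over the list alone. The list's median was 0.19 (adjusted p = 0.0283, and adjusted p = 0.529 with an estimated correlation), and the call was lost without replicate 2 before dox or replicate 1 at 24 h, at up to 0.0965.

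**Figure D2:**
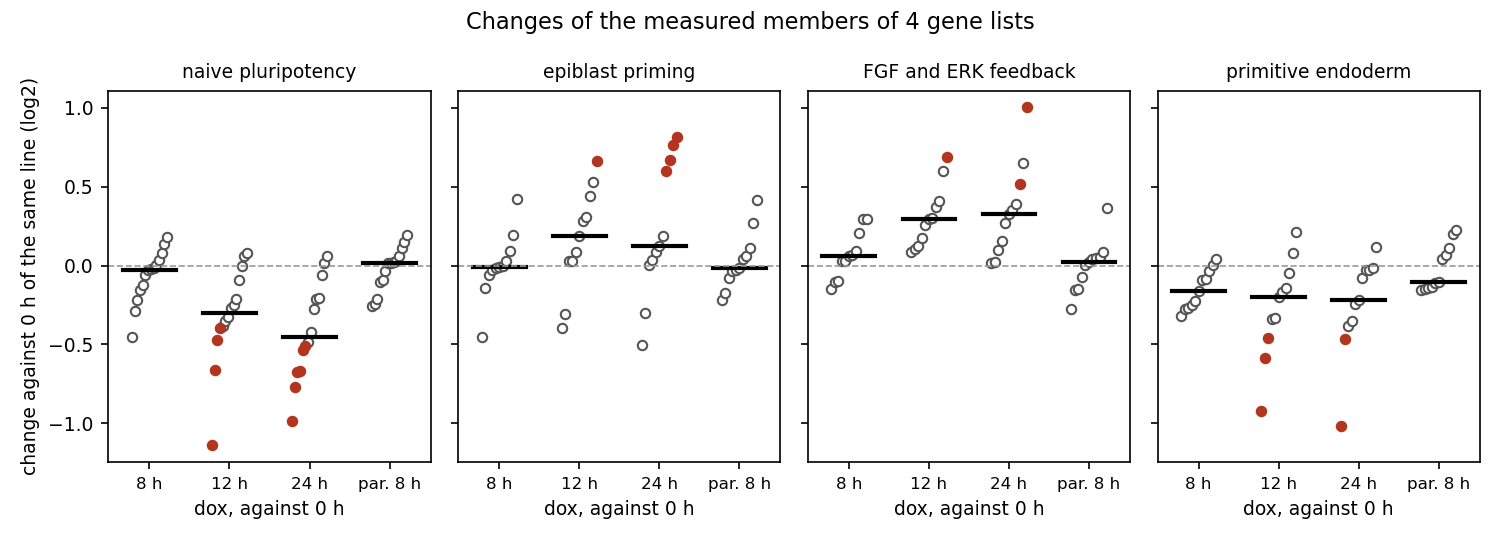
Log2 change against the untreated cells of the same line (y axis) for each measured gene of the naive pluripotency, epiblast priming, FGF and ERK feedback and primitive endoderm lists at 8, 12 and 24 h in Tcf15-E47 cells and at 8 h in parental cells (x axis), with genes at an adjusted p under 0.05 filled red and a black bar at each median. The fitted naive pluripotency median moves from −0.03 at 8 h to −0.30 at 12 h and −0.46 at 24 h.

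Single genes of other lists also changed at 24 h. Zeb1, a factor of mesenchymal cells, rose by 0.65, Mmp2, a matrix metalloproteinase, by 0.76 and Gadd45g by 0.65. Bmp4 (−0.57, with −0.10 on its other probe), Notch4 (−0.65) and Tfap2c (−0.73) fell. Dll1 was at least 1.55-fold higher and Krt7 at least 1.14-fold higher, while Ncam1 was at least 1.26-fold lower and Evx1 at least 1.23-fold lower. In Tcf15-E47 cells the fibroblast gene Dcn stood at 6.09 and 6.58 at 24 h against 5.73 and 5.71 without dox, without passing.

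In all, limma called 160 genes higher and 258 lower at 24 h, with a median size of 0.557 on the log2 scale, and 10 and 5 of them passed 2-fold. The share higher was 38.3%, and 73.1% with median scaling, which moved the median of all genes by 0.13 and gave 77 lower. The counts were 242 higher without background correction, 245 from the authors' values, 255 with trend and robust moderation, 162 lower without the filter, and 90 and 164 from only the arrays compared. With a single array left out they were 42 higher and 67 lower without replicate 1 before dox, 37 and 61 without replicate 2, 63 and 96 without replicate 1 at 24 h, and 52 and 108 without replicate 2. Of 46 named called genes, 21 passed with any compared array left out, among them Nanog, Nr5a2, Id3, Dusp4, Prr19, Ramp2, Hopx and Lama1 but not Fgf5 or Otx2, and 0 reversed. In at least 1 setting the calls of Tcf3, Pdzrn3, Emp1, Tbx3, Tfcp2l1, Tcl1, Prdm14, Utf1, Pou3f1, Pim2, Spry4, Sox7, Zeb1, Mmp2, Bmp4, Notch4, Ncam1, Evx1 and Krt7 were lost and the other 27 held. Sox2 passed without background correction, from the authors' values and with trend and robust moderation, at up to 0.0446.

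The 12 h and 24 h responses shared genes: 70 were higher at both and 132 lower at both, and 0 moved in opposite directions. Independence would give 4.87 and 12.1, but both comparisons use the same 2 untreated arrays and are not independent. The simulated groups were unchanged, so their 0 shared calls cannot show how much overlap the shared arrays add among called genes. In simulation the shared arrays alone gave the same sign in 66.7% of all genes against 70.6% observed, and r = 0.499 across genes against 0.631 observed. The 8 h and 24 h changes correlated at r = 0.417 against 0.501 from shared controls alone, with a covariance of 0.0125 against 0.00991. With 2 control arrays these cannot be split, so part of any excess may come from them. The r ran from 0.306 to 0.54 with 1 array left out.

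Between 8 h and 24 h of dox, 4 of 14 naive pluripotency genes fell and Dusp4, Otx2 and Fgf5 rose. Nanog fell by 0.53 ± 0.093 on the log2 scale (adjusted p = 0.012), Otx2 rose by 0.63 ± 0.102 (adjusted p = 0.0083), Fgf5 by 0.62 ± 0.129 (adjusted p = 0.0289) and Id3 by 0.47 ± 0.0991 (adjusted p = 0.0295). Tcf3 differed by −0.26 ± 0.199 (adjusted p = 0.543). Id1 (0.47, adjusted p = 0.0591), Sox2 (−0.21), Pou5f1 (−0.07), Id2 (0.04), Cdh1 (0.03) and Tcf15 (0.07) did not pass. Id1 passed without background correction, from the authors' values and with trend and robust moderation, at up to 0.0134. The largest rises were in Gbp2b at 1.20 ± 0.103, Ramp2 at 1.09, Dusp4 at 0.91, Gbp2 at 0.86 and Prr19 at 0.85. The largest falls were in Hopx at −1.16 ± 0.1, Mras at −1.16, the aspartic protease gene Napsa at −1.09, Gpr83 at −1.03 and the aldehyde dehydrogenase gene Aldh3a1 at −0.99. Adjusted p values of these 10 genes ran from 0.000151 to 0.00228.

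Of the 14 naive pluripotency genes, Tbx3 (−0.61), Tcl1 (−0.57), Nanog and Nr5a2 (−0.48) fell between 8 h and 24 h, and 7 fell adjusted over the list alone (list median −0.35, adjusted p = 6.05e-06, and adjusted p = 0.103 with an estimated correlation). Of 11 FGF and ERK feedback genes, Dusp4 and Dusp6 (0.50) rose, and 4 rose adjusted over the list alone (median 0.26, adjusted p = 0.0014, and adjusted p = 0.571 with an estimated correlation). Of 11 epiblast priming genes, Otx2 and Fgf5 rose, and 4 rose adjusted over the list alone (median 0.14, or 0.24 without 1 gene not above background in either group, adjusted p = 0.0112, and adjusted p = 0.527 with an estimated correlation). That call was lost without replicate 2 at 24 h, at 0.0588, and without the filter, at 0.0915. Of 14 integrated stress response genes, Chac1 rose by 0.58, and 2 rose adjusted over the list alone (median 0.15, adjusted p = 0.0312, and adjusted p = 0.529 with an estimated correlation). It was lost without replicate 2 at 8 h or replicate 1 at 24 h, at up to 0.133, and without the filter, at 0.101. Lama1 (−0.85), Lefty1 (−0.72), Tfap2c (−0.67) and Aldoc (−0.45) fell, while Krt18 (0.55), Gbx2 (0.43) and the fibroblast gene Dcn (0.76) rose.

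In all, limma called 66 genes higher and 158 lower at 24 h than at 8 h, with a median size of 0.582 on the log2 scale. The share higher was 29.5%, and 67.4% with median scaling, which moved the median of all genes by 0.102 and gave 43 lower. The counts were 121 higher without background correction, 122 from the authors' values, 154 and 286 with trend and robust moderation, 36 and 75 without the filter, and 24 and 51 from only the arrays compared. With a single array left out they were 12 higher and 15 lower without replicate 1 at 8 h, 15 and 38 without replicate 2, 20 and 34 without replicate 1 at 24 h, and 17 and 46 without replicate 2. Of 26 named called genes, 10 passed with any compared array left out, among them Gbp2b, Dusp4, Prr19, Ramp2 and Hopx but not Nanog, Otx2 or Fgf5. In at least 1 setting the calls of Nanog, Fgf5, Id3, Tbx3, Nr5a2, Tcl1, Tfap2c, Dusp6, Lama1, Krt18, Gbx2, Aldoc, Dcn and Chac1 were lost and the other 12 held.

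In parental cells 8 h of dox served as the control for dox itself at that time only, and no gene passed. Nanog differed by 0.19 ± 0.093 (adjusted p = 0.818, with −0.34 on its other probe), Tcf3 by 0.10 ± 0.199 (adjusted p = 0.971), Id3 by 0.11 ± 0.0991 (adjusted p = 0.932), Otx2 by −0.03 and Fgf5 by −0.17. Pou5f1 (−0.20), Sox2 (0.03), Id1 (−0.06), Id2 (−0.12), Cdh1 (0.04) and Tcf15 (−0.13) did not pass either. One of the 2 arrays, replicate 2 of the parental cells at 8 h, carried transcripts of fibroblast and smooth muscle genes. Acta2, the smooth muscle actin, stood at 11.03 there and at up to 5.48 on the other 11 arrays. Lox stood at 7.01, Col1a2 at 5.85, Col1a1 at 5.83 and Tagln at 5.37, all highest on that array.

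**Figure D3:**
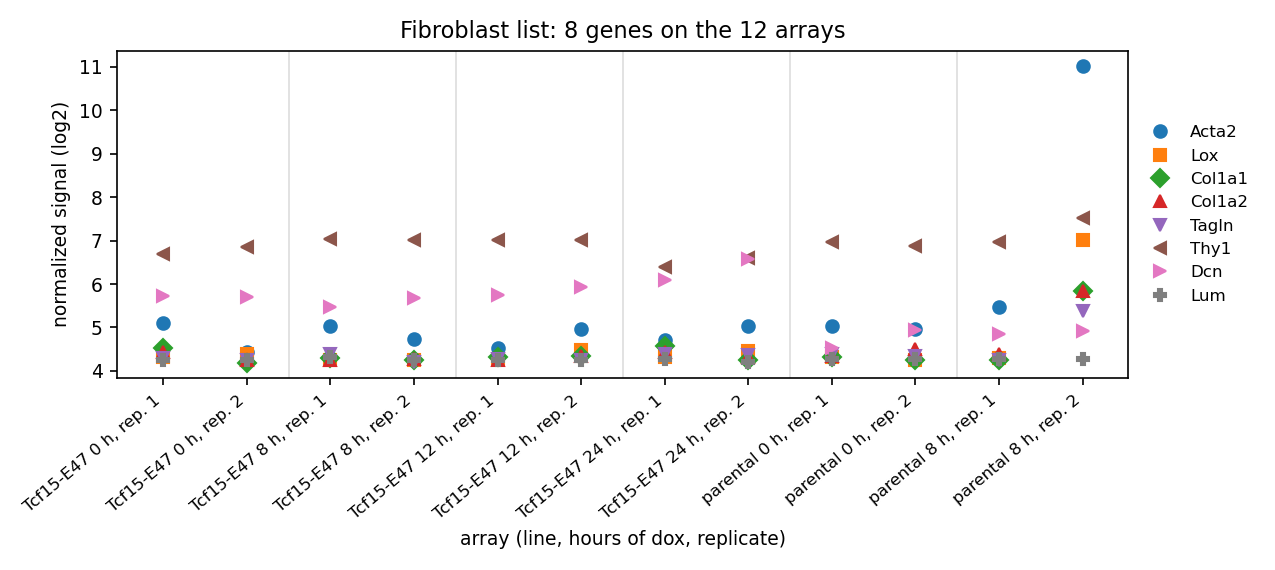
Normalized log2 signal (y axis) of the fibroblast list genes Acta2, Lox, Col1a1, Col1a2, Tagln, Thy1, Dcn and Lum on each of the 12 arrays (x axis). Replicate 2 of the parental cells at 8 h has Acta2 at 11.03 and Lox at 7.01, and Dcn is higher on the Tcf15-E47 arrays than on the parental arrays.

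For the parental cells limma called 0 genes higher and 0 lower, with 615 at an unadjusted p under 0.05 where chance gives 504.7 and a smallest adjusted p of 0.632. The counts were 11 and 3 with median scaling and 1 and 0 with trend and robust moderation. They were 0 and 0 without background correction, without the filter, with every kept probe, from only the arrays compared and from the authors' values. The deposited table of the authors likewise called 0 probes. Without replicate 1 before dox the counts were 2 and 22, and without replicate 1 at 8 h, which leaves the array with fibroblast transcripts, 15 and 0. Without that array they were 0 and 0. Of the 24 lists tested, 0 passed in parental cells.

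The 8 h response of Tcf15-E47 cells beyond that of parental cells tests whether the early differences exceed those with dox alone. Tcf3 differed by 1.10 ± 0.281 (adjusted p = 0.768), Prr19 by 0.95 ± 0.143 (adjusted p = 0.156), Nanog by −0.64 ± 0.131 (adjusted p = 0.491, with 0.01 on its other probe) and Id3 by 0.37 ± 0.14 (adjusted p = 0.937). Otx2 (0.00), Fgf5 (0.37), Id1 (0.22), Id2 (0.31), Pou5f1 (0.08), Sox2 (−0.22), Cdh1 (−0.10) and Tcf15 (0.16) did not pass. Tcf3 passed with median scaling, at 0.0143, and Nanog without background correction, from the authors' values and with trend and robust moderation, at up to 0.0251. The bHLH and Id list had a median of 0.23 over 8 genes (adjusted p = 0.0461, and adjusted p = 0.601 with an estimated correlation), with 1 gene rising adjusted over the list alone. Its call was lost without replicate 2 of any of the untreated Tcf15-E47, untreated parental or parental 8 h groups, or replicate 1 of the Tcf15-E47 8 h group, at up to 0.41. It was also lost with median scaling at 0.0923, without the filter at 0.344 and from only the arrays compared at 0.0528. The fibroblast transcripts on 1 parental array enter this comparison too, with Acta2 at 11.03 there.

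For this difference limma called 0 genes higher and 0 lower, with 514 at an unadjusted p under 0.05 where chance gives 504.7. The counts were 1 and 1 without background correction and from the authors' values, where they were Ccno and Nanog. They were 1 and 5 with median scaling, 2 and 1 with trend and robust moderation, and 0 and 0 without the filter, with every kept probe and from only the arrays compared. Without replicate 1 of the untreated parental cells they were 1 and 0, without replicate 1 at 8 h 1 and 9, and without replicate 2 at 8 h 0 and 0.

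Without dox the Tcf15-E47 cells already differed from the parental cells. Usp26, a ubiquitin-specific protease gene, was 5.0-fold higher, at 7.64 against 5.32 (log2 difference 2.32 ± 0.103, adjusted p = 8.75e-08). Fgf5 was lower by −0.95 ± 0.129 (adjusted p = 0.00234), and Id2 was higher by 0.68 ± 0.125 (adjusted p = 0.0121). Tcf3 (0.14, adjusted p = 0.722), Tcf15 (−0.16, adjusted p = 0.379), Nanog (0.18, adjusted p = 0.272), Otx2 (−0.01), Id1 (0.05), Id3 (−0.08), Pou5f1 (0.07), Sox2 (0.13) and Cdh1 (0.15) did not pass. Plac8 was higher by 1.33 ± 0.112, the metallothionein gene Mt3 by 1.09, or 0.66 (adjusted p = 0.109) without replicate 2 of the parental cells, the lactate dehydrogenase gene Ldhc by 1.01 and Usp9y by at least 1.27-fold. Wnt7b, a WNT ligand, was lower by −1.51 ± 0.191, the iron exporter gene Slc40a1 by −1.09, Rhox9 by −1.08 and Fbxw7 by −1.03 with −0.09 on its other probe, or −0.67 without replicate 2 of the parental cells. Foxq1 was at least 1.68-fold lower. Adjusted p values of these 10 genes ran from 8.75e-08 to 0.0196.

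Of 11 primitive endoderm genes, Sox7 (−0.81), Amn (−0.67), Col4a2 (−0.54) and Col4a1 (−0.51) were lower in untreated Tcf15-E47 cells, and 6 were lower adjusted over the list alone (median −0.33, adjusted p = 0.00633, and adjusted p = 0.564 with an estimated correlation). Of 11 FGF and ERK feedback genes, Phlda1 (−0.58), Ier3 (−0.57) and Dusp4 (−0.51) were lower, and 5 adjusted over the list alone (median −0.35, adjusted p = 0.00479, and adjusted p = 0.608 with an estimated correlation). Without replicate 1 of the untreated parental cells these calls were lost, at 0.116 and 0.0608. Of 7 immediate early genes, Zfp36 (−0.41) was lower, and 2 adjusted over the list alone (median −0.35, adjusted p = 0.0312, and adjusted p = 0.564 with an estimated correlation). Without replicate 1 of the Tcf15-E47 cells or replicate 2 of the parental cells it was lost, at up to 0.154, and without the filter, at 0.101. Klf5 (−0.61), Tbx3 (−0.51) and Klf4 (−0.46) were lower among 14 naive pluripotency genes, a list that did not pass (adjusted p = 0.567). Without replicate 1 of the parental cells Tbx3 was at −0.31 (adjusted p = 0.186) and Col4a1 at −0.31 (adjusted p = 0.23). Evx1 (−0.73), Tfap2c (−0.71) and Ddit4 (−0.47) were lower and Dll1 was at least 1.28-fold lower, while Pcna (0.50) and Phgdh (0.55) were higher. Of the markers of other cells, the fibroblast gene Dcn was at least 1.61-fold higher.

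In all, limma called 249 genes higher and 307 lower in untreated Tcf15-E47 cells, with a median size of 0.517 on the log2 scale, and 5 and 6 of them passed 2-fold. The share higher was 44.8%, and 76.4% with median scaling, which moved the median of all genes by 0.0965 and gave 54 lower. The counts were 389 higher with trend and robust moderation, 147 higher without the filter, and 58 and 91 from only the arrays compared. With a single array left out they were 24 higher and 59 lower without replicate 1 of the Tcf15-E47 cells, 34 and 53 without replicate 2, 161 and 168 without replicate 1 of the parental cells, and 75 and 112 without replicate 2. Of 30 named called genes, 10 passed with any compared array left out, among them Usp26, Plac8, Usp9y, Wnt7b, Fgf5 and Sox7. In at least 1 setting the calls of Mt3, Klf4, Klf5, Tbx3, Col4a1, Col4a2, Amn, Dusp4, Ier3, Phlda1, Zfp36, Evx1, Ddit4, Pcna, Phgdh and Dll1 were lost and the other 14 held. Of the genes called both here and at 24 h, 61 moved in opposite directions, 2 were higher in both and 22 lower in both, where the same untreated arrays serve both comparisons with opposite sign and alone gave r = −0.502 against −0.259 observed.

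Across the 7 comparisons, 20 of 168 list tests passed with the preset correlation and 0 with an estimated one. In 16 lists no comparison passed, with a smallest adjusted p of 0.0712: general pluripotency, trophoblast, neural progenitor and neuron, epithelial genes, mesenchymal and motility genes, lymphoid E-protein targets, blood and endothelium, 2-cell-like and germ cell, cell cycle arrest and p53 targets, proliferation, WNT targets, NOTCH pathway, BMP and NODAL targets, LIF and STAT3 targets, hypoxia and glycolysis, and cholesterol synthesis. Primitive streak, paraxial mesoderm and skeletal muscle genes with 3 measured members each and fibroblast genes with 4 were too few for the test.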

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

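All tests of explanations in this part were chosen only after the results were seen. The gene lists and comparisons were fixed beforehand.

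Some results differed between time points or lines by a test of the difference itself. Between 24 h and 8 h of dox, 66 genes were higher and 158 lower. The lists that differed between these times were naive pluripotency (camera adjusted p = 6.05e-06), FGF and ERK feedback (0.0014), epiblast priming (0.0112) and the integrated stress response (0.0312). The 8 h responses of both lines to dox differed in the bHLH and Id list (0.0461). All of these list calls were lost with an estimated correlation.

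A signal also lay in probes that the filter had removed: 13 of them were over 2 log2 units above every other array on replicate 2 of the parental cells at 8 h, against 0 on each other array. The genes Bgn (9.53) and Mgp (8.46) were noticed there, beside Acta2 (11.03) of the fibroblast list. The tables argue against a response to dox, since the mean change of the fibroblast list was 1.16 on that array, 0.04 on the other parental array at 8 h and at most 0.0787 on the other 7 dox arrays. RNA of other cells on that array may be the source: 7 of the 12 fibroblast list genes were highest there, among them Col3a1, which was not detected. Lum, Postn and Pdgfrb were not detected either and Col1a1 reached 5.83, so that a kind of cell cannot be read from the list. RNA of other cells cannot be told apart from another source of RNA for this array, because no test names the cell. Of biological explanations, a response to dox was the one tested. Lox, Thy1 and Tagln were highest there too.

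The genes lower at 12 h, 474 in all, had a median change of −0.545 and tended to be long, with a median span of 45.9 kb against 21.5 kb for all genes. How many genes were called lower depended on the scaling between arrays. Of the called genes 39.3% were higher, and 60% with median scaling, which moved the median of all genes by 0.0885. The tests below do not cover the scaling. An average trend over gene span as the whole cause is argued against. With that trend removed, the median of the 382 named genes lower at 12 h was −0.514 against −0.533 before, and 317 (83%) still passed. These genes were chosen for their fall, so this speaks only to the trend across all genes. Transcript length was not tested. The 12 h arrays lay −0.466 below the 8 h arrays in the same genes. Since the 12 h arrays helped choose these genes, that value cannot decide whether the untreated arrays stand apart. Neither the 24 h nor the 8 h arrays chose the genes. Of these genes 83.3% were lower at 24 h than at 8 h, against 50.4% of all genes, with a median of −0.219. That argues against the 12 h arrays, or the untreated arrays, standing apart as the whole cause. The larger fall at 12 h stays open, and so does a response to Tcf15-E47 that peaks then, which was not tested.

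The FGF and ERK feedback genes were lower in untreated Tcf15-E47 than in untreated parental cells, with a median of −0.345 and 10 of 11 lower. A leak of the construct without dox stays open. The list was higher at 24 h than at 8 h of dox, the opposite direction to the difference between the untreated lines. The median of that rise was 0.262 (camera adjusted p = 0.0014, and adjusted p = 0.571 with an estimated correlation). Without parental arrays at 24 h it cannot be told apart from dox itself or time in culture, so it cannot decide. At 8 h the list's median response beyond parental cells was 0.04. A chance level of the untreated arrays also stays open. At 8 h of dox the lines differed by a median of −0.341 with quartiles of −0.48 and 0.0536 (camera p = 0.00929, not adjusted, and 0.241 with an estimated correlation), but by −0.0554 (camera p = 0.139) without replicate 2 of the parental cells, the array with fibroblast transcripts, and by −0.311 (camera p = 0.0738) without replicate 1 of the Tcf15-E47 cells. A difference between the lines from before, or from picking a clone, may account for it and was not tested.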

How the results depend on the processing

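The fits without replicate 2 of the parental cells at 8 h and without the 12 h arrays were chosen after the results were seen. So was the fit on the entries of the non-normalized table. All others were fixed beforehand, apart from the recovery of probe signals by value. Of 143 named called values 0 reversed in the refits whose kept calls are counted next, or with the replicate block. Reversals were not counted for the other alternatives, such as every kept probe. At 24 h other probes of Tcl1 and Sox7 had positive values where the probe tested fell, as given above. Kept calls numbered 131 without background correction and from the authors' values, 138 with trend and robust moderation, 114 from only the arrays compared, 106 with median scaling, 98 without the filter and 58 with each compared array left out. Signal close to background limits dim genes. Counts are given as higher and lower, and the cause of a changed count was not tested except where fewer genes or arrays make it.

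Without background correction the counts were 3 and 1 at 8 h, 479 higher at 12 h, 242 higher at 24 h, 121 higher at 24 h against 8 h, and 1 and 1 beyond parental cells. From the authors' values they were 3 and 1, 490, 245, 122, and 1 and 1 in the same order. With median scaling they were 1 higher at 8 h, 172 lower at 12 h, 77 lower at 24 h, 43 lower at 24 h against 8 h, 11 and 3 in parental cells, 1 and 5 beyond parental cells, and 54 lower between the lines. Without the filter they were 2 higher at 8 h, 162 lower at 24 h, 36 and 75 at 24 h against 8 h, and 147 higher between the lines. With trend and robust moderation they were 4 and 1 at 8 h, 466 higher at 12 h, 255 higher at 24 h, 154 and 286 at 24 h against 8 h, 1 higher in parental cells, 2 and 1 beyond parental cells, and 389 higher between the lines. From only the arrays compared, with fewer degrees of freedom, they were 90 and 164 at 24 h, 24 and 51 at 24 h against 8 h, and 58 and 91 between the lines. With every kept probe 2 genes were higher at 8 h, and 3 were when the entries of the non-normalized table were fitted. Calls that also passed 2-fold were 5 and 20 at 12 h, 10 and 5 at 24 h, 2 and 4 at 24 h against 8 h, and 5 and 6 between the lines. With an estimated correlation 0 lists were called. Without the 12 h arrays the counts were 124 and 203 at 24 h, 44 and 108 at 24 h against 8 h, and 178 and 216 between the lines.

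With 1 array left out, counts ran from 0 to 0 higher and lower at 8 h, 58 to 280 higher and 127 to 423 lower at 12 h, 37 to 143 and 61 to 239 at 24 h, and 12 to 68 and 15 to 150 at 24 h against 8 h. They ran from 0 to 15 and 0 to 22 in parental cells, 0 to 1 and 0 to 9 beyond parental cells, and 24 to 200 and 53 to 248 between the lines. Lists called ran from 14 to 21 and the correlation of the 8 h and 24 h changes from 0.306 to 0.54. The upper ends at 12 h, 24 h, 24 h against 8 h and between the lines come from leaving out replicate 2 of the parental cells at 8 h. These comparisons do not contain that array, and every other array was left out only for comparisons that contain it. These upper ends therefore do not show how far calls fall when a compared array is lost. The counts with each compared array left out, given with each comparison, were all lower.

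The replicate numbers do not pair the samples: of 15 pairs of groups, 3 had deviations correlated over 0.1, with a range of −0.1 to 0.17. A replicate block gave 0 and 0 at 8 h, 304 and 466 at 12 h, 147 and 240 at 24 h, 52 and 136 at 24 h against 8 h, 0 and 0 in parental cells and beyond them, and 214 and 263 between the lines, with 19 lists called and r = 0.417. With the block 4 named calls were lost, and the bHLH and Id list beyond parental cells did not pass (adjusted p = 0.0646).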

Other observations

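All of the gene groups in this part were chosen only after values had been seen, and no explanation was tested for them.

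Of 16 interferon-related genes, 5 rose at 24 h of dox, 0 fell and 11 did not pass, and the group as a whole was not tested. Gbp2b rose by 1.01 ± 0.103, Gbp2 by 0.84 ± 0.11 and Irf1 by 0.68 ± 0.0991. Oasl2 and Gbp3 were not well above background without dox and were at least 1.19-fold and at least 1.17-fold higher. These 5 had limma adjusted p values from 0.00025 to 0.0472. Irf9 (−0.20), B2m (−0.04) and H2-T23 (−0.01) had negative values. At 12 h 2 of them rose, Gbp2b by 0.47 and Irf1 by 0.39. With 8 h of dox 0 were called in either line, and parental cells were not measured later. Without dox, Gbp2b (−0.71) and Gbp2 (−0.54) were lower in Tcf15-E47 than in parental cells, and Gbp3 was at least 1.23-fold lower.

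Of 7 mitochondrially encoded transcripts, 4 fell at 24 h: COX2 fell by 0.98 ± 0.147, ND4 fell by 0.63 ± 0.118 and ND1 fell by 0.45 ± 0.107 on the log2 scale, and ND4L, not well above background at 24 h, was at least 1.31-fold lower, with limma adjusted p values from 0.00309 to 0.0458. ND5 (0.00), ATP6 (0.02) and CYTB (−0.32, adjusted p = 0.117) did not pass, so the group did not move as 1. At 12 h COX2 fell by 0.67.

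Without dox the lines differed in Usp26 and in 2 of the 3 Y-linked genes looked at, Usp9y and Eif2s3y. Usp9y stood at 5.38 in Tcf15-E47 and 4.22 in parental cells, where it was not well above background, Eif2s3y at 8.99 and 8.45 (adjusted p = 0.0204), Uty at 5.04 and 4.98 (adjusted p = 0.884), and Usp26 at 7.64 and 5.32. None of these 4 genes was called at 8, 12 or 24 h of dox.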
